A study of Bombyx mori with 4 samples.

How the data were processed

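ATAC-seq, which uses a transposase to cut and tag open chromatin, was run on nuclei of the brain and the fat body of larvae of the silkworm Bombyx mori, strain P50. The fat body is the insect organ that stores lipid, glycogen and protein and secretes most haemolymph proteins. There were 4 libraries, 2 per tissue, and the titles number them 1 and 2 within each tissue; they are called brain 1, brain 2, fat body 1 and fat body 2 here. The labels do not say whether the libraries of a tissue came from separate animals or dissections, so the spread between them is not known to be that of animals. Per the labels' protocols, nuclei were released with a Dounce homogenizer, and tagmentation used a pA-Tn5 transposome.

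For each library the deposited data used here were 1 list of peaks. Per the submitters' processing notes, Trim Galore, Bowtie2, Picard, deepTools 3.3.0 and MACS2 2.1.0 were used. Apart from a mapping quality of 20 in the peak names, their settings are not given in the sources used here. Neither are the read counts and the name of the genome build. The sequence names in the lists start with BHWX01. Sequences numbered 1 to 28 reached from 8.36 to 21.5 Mb and are called long sequences; higher numbers, none longer than 0.288 Mb, are called unplaced. In the deposited lists each peak has the fold enrichment that MACS2 gives for the summit over local background, a −log10 p, a −log10 q, an integer score and the summit offset. The deposited score was 10 times −log10 p in 3 lists and 10 times −log10 q in fat body 2. The lists were also cut differently by the authors. The lowest −log10 p was 5.01 in brain 1, 5.03 in brain 2 and 5.01 in fat body 1, while fat body 2 had a lowest −log10 p of 6.69 and a lowest −log10 q of 5.04. Peaks were listed per library, not on pooled reads. Fold, p and q belong to 1 library and were used only to describe, rank or filter peaks within a list.

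No read depth stands in a peak list. A summit's fold and −log10 p together fix its read pile-up and its local background, taking fold as (pile-up + 1) / (background + 1) and p as the Poisson chance of more reads than the pile-up. Whole pile-ups from 2 to 1000 were searched for every peak with a −log10 p under 250. Exactly 1 whole pile-up met both values within a relative tolerance of 2e-05 for 100.0% of the searched peaks of each list (35630, 11552, 106203 and 14387 peaks in brain 1, brain 2, fat body 1 and fat body 2). The lowest background found in a list was taken as its genome-wide floor. The floor scales with the number of reads and with the fragment length that MACS2 assumed, so it is not a read count. The floor divided by the length of the shortest peak of a list was given beside it.

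Peaks that overlapped by at least 1 bp were merged over the 4 lists, and a merged region was called present in a list if a peak of that list overlapped it. Brain-only regions were present in both brain lists and neither fat body list, and fat-body-only regions the reverse. The overlap of 2 lists was measured as the Jaccard index, the bases in both lists divided by the bases in either, and as the share of the shorter list overlapped by the longer. Chance overlap was the mean over 100 random rotations of the shorter list along each sequence. Shares have exact binomial 95% intervals (Clopper-Pearson). Odds ratios have 95% intervals from the normal approximation of their logarithm and two-sided Fisher's exact tests. Intervals of background ratios come from 1000 bootstrap draws of peaks, and bins of 1 Mb with fewer than 5 peaks were left out. These intervals and tests cover counting over regions, which are not replicates; with 2 libraries per tissue, the 4 libraries can be split into pairs in only 3 ways, so the smallest p for a difference between tissues over libraries is 0.333 and no such test is given. Within each tissue number, a region present in 1 tissue and absent in the other was given that tissue's direction, and the directions of the pair numbered 1 and the pair numbered 2 were compared.

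Before the data were examined, the comparisons, the alternatives and the rule for named regions were fixed: the 5 tissue-only regions per tissue with the best mean percentile of −log10 q within the lists of that tissue. The comparison of directions within numbers, the pairs with different numbers, the look-up of one number's regions in the other, the overlap divided by chance, and every statement by sequence or position were added after the lists were seen, though the prediction for the background in bins of sequence 1 was written before its result. Planned comparisons of promoters, 18 gene lists and G-quadruplex motifs need a genome and gene models of the same build and were not analysed here. For that reason regions are given by coordinates (1-based, as in the deposited lists) and not by gene. Coordinates of the reference table at hand belong to another assembly and were not used.

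Alternatives were a −log10 q of at least 5 in every list, the 11572 best peaks of each list, an overlap of 50%, windows of 100 bp each side of the summits, the 28 long sequences alone, and leaving out each library. The interval, pattern and pile-up code was tested on simulated data: it recovered 100.0% of 20000 simulated region patterns and 100.0% of 2151 simulated pile-ups, and returned direction odds ratios of 0.996 and 9.20 where 1 and 9 had been simulated. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.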

Results

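Accessible chromatin was mapped in the brain and the fat body of silkworm larvae of strain P50, all titled with the stage code L5D3, with 2 ATAC-seq libraries per tissue. Brain 1 had 36420 peaks covering 18.2 Mb, and brain 2 had 11572 peaks covering 5.98 Mb. Fat body 1 had 107057 peaks covering 21.8 Mb, and fat body 2 had 14752 peaks covering 9.53 Mb. The peaks of fat body 1 were the shortest, with a median width of 166 bp against 425 bp in brain 1, 491 bp in brain 2 and 637 bp in fat body 2. Median fold enrichment at the summit, as the authors' peak caller gave it, was 5.62 in brain 1, 5.40 in brain 2, 4.01 in fat body 1 and 8.59 in fat body 2. The peak names of brain 1 carry the stage code 5L-4D, whereas those of brain 2 and fat body 1 carry 5l3d and those of fat body 2 carry L5D3. The codes thus follow neither tissue nor number. If the code of brain 1 stands for another day than its label, every comparison of brain 1 with another library, the brain-only regions and the direction of tissue differences included, mixes stage with tissue or replicate.

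The background floor of the lists followed the library number and not the tissue. Recovered from the summits, it was 1.38 reads of pile-up in brain 1 and 1.38 in fat body 1, against 0.558 in brain 2 and 0.534 in fat body 2. The floor of number 1 was thus 2.47 times that of number 2 in brain and 2.59 times in fat body (2.80 and 5.84 times per bp of the shortest peak), while within a number the tissues differed by a factor of 1.00 or 1.04. The shortest peak was 94 bp in fat body 1 and between 203 and 230 bp in the other lists. Per bp of the shortest peak, the floor of fat body 1 was 2.17 times that of brain 1, and the floor of fat body 2 was 1.04 times that of brain 2. The floor alone therefore does not show that the libraries of number 1 had the same depth, and fat body 1 had 2.94 times as many peaks as brain 1.

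The first comparison was whether the libraries of a tissue shared their open regions. Of the 11572 regions of brain 2, 4475 were found in brain 1, or 38.7% (95% interval 37.8 to 39.6), where random rotations gave 8.10%. Of the 14752 regions of fat body 2, 5496 were found in fat body 1, or 37.3% (36.5 to 38.0), where random rotations gave 18.6%. The share overlapped between tissues within a number was higher. Brain 2 shared 66.5% of its regions with fat body 2 (chance 4.12%), and brain 1 shared 52.6% with fat body 1 (chance 16.0%). Relative to chance, however, the brain pair, at 4.78 times, exceeded brain 1 with fat body 1, at 3.3 times, while brain 2 with fat body 2 reached 16.1 times. The fat body pair, at 2.0 times, lay below both and below brain 2 with fat body 1, at 2.85 times, which share neither tissue nor number. A share cannot exceed the whole list, so this ratio has a lower ceiling where chance is higher. Chance was 8.10% for the brain pair and 16.0% for brain 1 with fat body 1. The order of the ratios therefore does not by itself rank the pairs. Brain 2 also shared more of its regions with fat body 1, 46.3%, than with brain 1.

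By the unscaled Jaccard index the 4 lists were ordered by number before tissue. The index was 0.359 for brain 2 with fat body 2 and 0.121 for brain 1 with fat body 1, a mean of 0.240 ± 0.168 (SD, n = 2 pairs). It was 0.0785 for the brain lists and 0.0398 for the fat body lists, a mean of 0.0592 ± 0.0274 (SD, n = 2 pairs). The lists that shared neither tissue nor number had 0.0455 (brain 2 with fat body 1) and 0.0221 (brain 1 with fat body 2), a mean of 0.0338 ± 0.0165 (SD, n = 2 pairs). The mean of the same-tissue pairs minus that of all 4 different-tissue pairs was -0.0778. Restricted to pairs of libraries with different numbers, the difference turned to 0.0253 in favour of the same tissue, which is smaller than the SD of the same-tissue pairs. Divided by the index of random rotations, brain 2 with fat body 2 stayed highest, at 39.7, but the brain pair, at 7.85, lay above brain 1 with fat body 1, at 5.32, and the fat body pair, at 2.66, lay below brain 2 with fat body 1, at 4.30. With the 11572 best peaks of each list, brain 1 had an index of 0.131 with fat body 1 and 0.130 with brain 2, or 25.7 and 17.3 over chance, so the order of these pairs depends on the scale and on the list length. The fat body pair was then 10.4 over chance, against 15.7 for brain 2 with fat body 1.

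**Figure D1:**
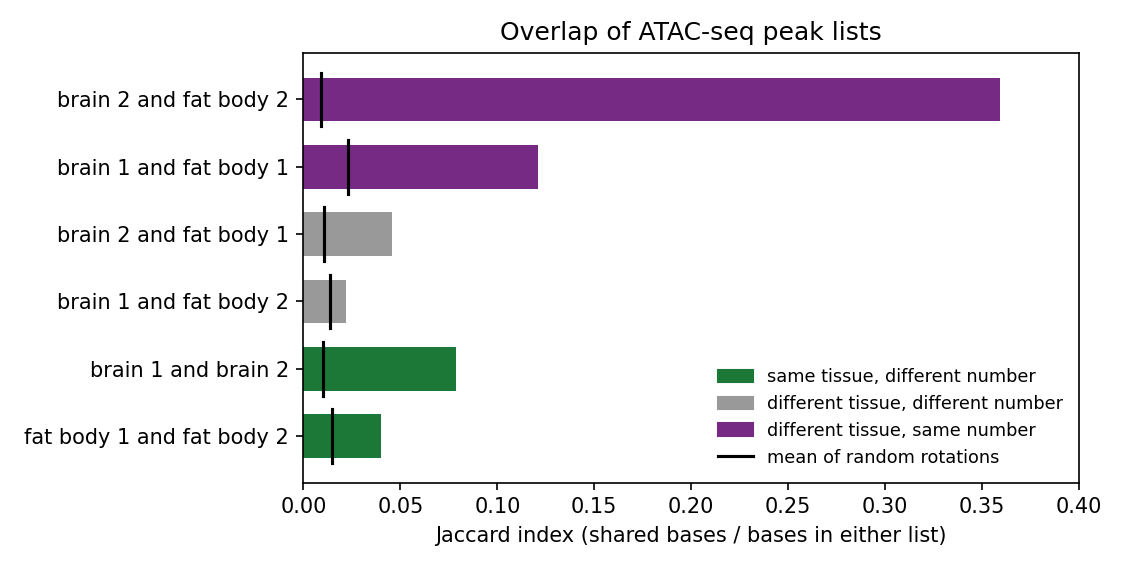
Jaccard index of each pair of peak lists (bars), coloured by whether the pair shared its tissue or its library number, with the mean of 100 random rotations as a black line. The pairs that shared a number, 0.359 and 0.121, lie above every pair that did not.

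The second comparison was the difference between the tissues. Merging the 4 lists gave 130309 regions, of which 101492 were present in 1 list and 1075 in all 4. Brain-only regions numbered 654 and had a median width of 670 bp, and fat-body-only regions numbered 2013 and had a median width of 792 bp. Both counts were exceeded by regions that shared a number and not a tissue: 14809 were present in brain 1 and fat body 1 alone and 4677 in brain 2 and fat body 2 alone. The class of 14809 joins the long lists of number 1 (36420 and 107057 peaks). Each tissue-only class needs a shorter list of number 2 (11572 or 14752 peaks), and list length was not matched in these counts. The other mixed pairs were rarer than either tissue-only class, with 184 regions in brain 2 and fat body 1 alone and 144 in brain 1 and fat body 2 alone. No chance level was computed for any of these counts. Random rotations of fat body 2 overlapped fat body 1 for 18.6% of regions, and those of brain 2 overlapped brain 1 for 8.10%. Rotations of brain 1 overlapped fat body 1 for 16.0%, and those of brain 2 overlapped fat body 2 for 4.12%. Part of the tissue-only regions, above all the fat-body-only ones, may therefore be coincidental overlap. The same holds for the regions of brain 1 and fat body 1 alone. Which tissue had more of its own regions depended on the processing: with the 11572 best peaks from each list there were 1676 brain-only and 743 fat-body-only regions, and with an overlap of at least 50% there were 1382 and 735.

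**Figure D2:**
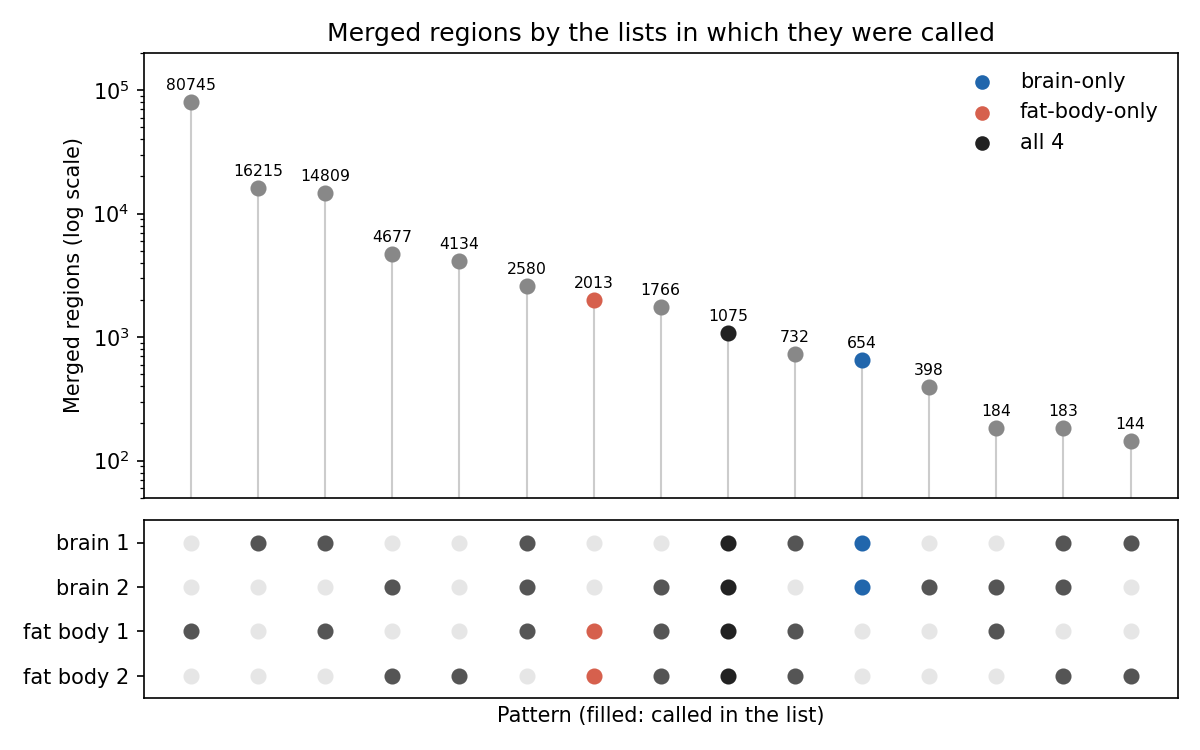
Number of merged regions (log scale) for each of the 15 patterns of presence in the 4 lists; filled circles below mark the lists in which the regions were called. Brain-only (654), fat-body-only (2013) and common regions (1075) are coloured, and the largest class of 2 lists is that of brain 1 with fat body 1 (14809).

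Most regions that differed between the tissues within both library numbers did so in the same direction. In the pair numbered 1, 17196 regions were called in brain and not in fat body and 84708 in fat body and not in brain. In the pair numbered 2 these counts were 3816 and 7023. A region differed in both pairs in 2995 cases. Of these, 654 were brain regions in both pairs and 2013 were fat body regions in both, and 328 pointed in opposite directions. The directions thus agreed for 89.0% of the regions (95% interval 87.9 to 90.1), against 60.3% if the pairs were independent. The odds ratio was 49.7 (39.3 to 62.9) by Fisher's exact test, with a two-sided p below the smallest number the software represents. It stayed between 36.9 and 1064 under the other settings, and was 47.1 without sequence 1. The same odds ratio for number, over regions that differed between numbers in both tissues, was 2614 (2097 to 3259). Both odds ratios divide by the same 144 and 184 regions, and the number 1 lists were the longer ones, so the sizes of the odds ratios are not compared. Most regions that differed between tissues in 1 pair did not differ in the other and lie outside the tissue odds ratio. Regions in both number 2 lists were called in fat body 1 and not brain 1 in 1766 cases, and the reverse in 183. For fat body 2 without brain 2 these counts were 2013 and 144. For brain 2 without fat body 2 they were 184 and 654. The shift from the shared regions was thus larger for brain.

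The regions that brain 2 had and fat body 2 lacked were found again in brain 1 more often than the other regions of brain 2. Of the 3816 regions that brain 2 had and fat body 2 lacked, 84.7% were present in brain 1 (95% interval 83.6 to 85.9). Of the 7701 regions that brain 2 and fat body 2 shared, 16.3% were (15.5 to 17.2), and of the 7023 that fat body 2 had and brain 2 lacked, 12.5% were (11.7 to 13.3). The odds ratio of presence in brain 1 was 28.5 (25.6 to 31.7) for the first class against the shared one. The regions of brain 2 without fat body 2 were also present in fat body 1 in 72.4% of cases, so most were not particular to brain. This was more often than the regions fat body 2 had to itself, at 39.1%, and the shared regions, at 36.9%. The odds ratio of presence in fat body 1 against the shared regions was 4.49 (4.13 to 4.89). For presence in fat body 1, the regions that fat body 2 had to itself exceeded the shared regions by an odds ratio of 1.10 only (1.03 to 1.17). In the reverse look-up the shared regions were found more often. Of regions in brain 1 and not fat body 1, 4.87% were in brain 2, against 19.0% of those in both. Of regions in fat body 1 and not brain 1, 4.46% were in fat body 2, against 9.41% of those in both.

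The 5 named brain-only regions lay on different long sequences. The first, on BHWX01000025.1 from 10205459 to 10206064 (606 bp), had a fold enrichment of 14.5 in brain 1 and 12.5 in brain 2, and the summit lay at 10205758 in both. The second, on BHWX01000015.1 from 1064433 to 1064969, had 11.3-fold and 10.4-fold enrichment in brain 1 and brain 2. The third, on BHWX01000006.1 from 6249424 to 6249973, had 17.9-fold and 10.8-fold enrichment. The fourth, on BHWX01000023.1 from 16764751 to 16765707, had 15.3-fold and 9.70-fold enrichment. The fifth, on BHWX01000020.1 from 5748969 to 5749614, had 17.5-fold and 8.15-fold enrichment. Over all brain-only regions the median fold was 9.59 in brain 1 and 4.42 in brain 2. Their median percentile of −log10 q was 86.2 in brain 1 and 36.1 in brain 2, lists of unequal length whose percentiles are not comparable. The summits of the brain libraries lay a median of 75 bp apart, and within 100 bp in 60.2% of the brain-only regions. Regions of brain 1 and fat body 1 alone had summits a median of 44 bp apart, with 66.4% within 100 bp, and regions of brain 2 and fat body 2 alone 79 bp, with 57.0%.

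The 5 named fat-body-only regions also lay on different long sequences. The first lay on BHWX01000015.1 from 9780812 to 9781119 (308 bp), with 36.6-fold enrichment in fat body 1 and 23.0-fold in fat body 2 and the summit at 9780958 in both. The second lay on BHWX01000017.1 from 2860464 to 2860736, with 35.6-fold and 22.5-fold enrichment. The third lay on BHWX01000021.1 from 11528730 to 11529277, with 19.8-fold and 16.0-fold enrichment. The fourth lay on BHWX01000010.1 from 3659066 to 3659361, with 28.1-fold and 19.4-fold enrichment and a shared summit at 3659212. The fifth lay on BHWX01000008.1 from 5466439 to 5466804, with 25.2-fold and 17.4-fold enrichment. Over all fat-body-only regions the median fold was 4.30 in fat body 1 and 7.86 in fat body 2, and the median percentile was 59.5 and 44.9. Their summits lay a median of 80 bp apart, and within 100 bp in 55.9% of the regions.

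The 1075 regions open in all 4 libraries had a median percentile of −log10 q of 95.5 in brain 1, 69.6 in brain 2, 97.8 in fat body 1 and 67.1 in fat body 2. These percentiles are not compared between lists, because the lists differ in length and in how they were cut. Their median width was 902 bp. The region with the best mean percentile, picked after the lists were seen, lay on BHWX01000014.1 from 4979244 to 4981197, with 10.7-fold enrichment in brain 1, 9.83-fold in brain 2, 22.9-fold in fat body 1 and 21.6-fold in fat body 2.

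The strongest peaks were found again in the other library of the tissue more often than the weakest ones in every list but brain 2. Peaks were ranked by −log10 q and cut into 10 parts of equal size. Of the strongest part of brain 1, 66.8% was found in brain 2 (95% interval 65.2 to 68.3), and of the weakest part 2.58% (2.09 to 3.15). Of the strongest part of fat body 1, 18.2% was found in fat body 2 (17.5 to 19.0), and of the weakest 4.68% (4.29 to 5.10), with a low of 3.09% (2.77 to 3.44) in the part after the strongest. The strongest part of brain 2 was found in brain 1 for 29.7% (27.1 to 32.5), which was not above the weakest part, at 33.4% (30.7 to 36.2). It was found in fat body 2 for 88.9% (86.9 to 90.6). The strongest part of fat body 2 was found in fat body 1 for 39.5% (37.0 to 42.1), against 22.2% (20.1 to 24.4) of its weakest part, and in brain 2 for 73.0% (70.7 to 75.3). No chance level was computed per part, and peak width was not matched between parts. Random rotations of the whole fat body 2 list overlapped fat body 1 for 18.6%, not far below the share of its weakest part.

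**Figure D3:**
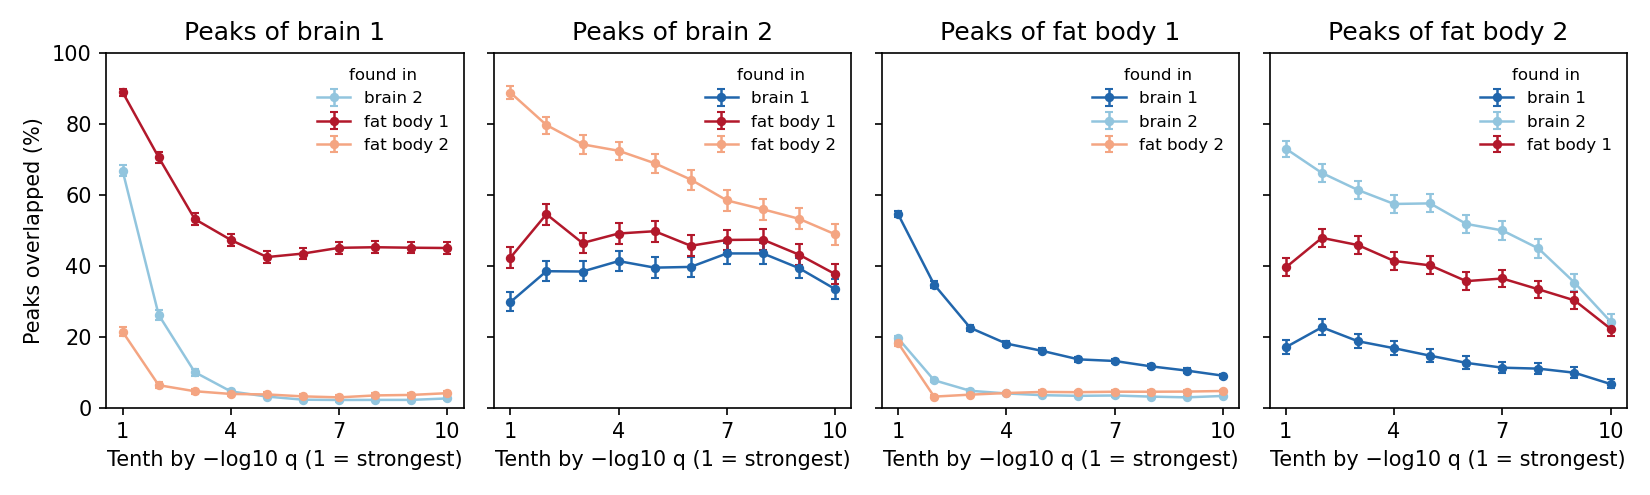
Share of the peaks of each list that another list overlapped (y axis, percent), by rank of the authors' −log10 q within the list in 10 parts (x axis, 1 is the strongest); points are shares and bars exact binomial 95% intervals. The strongest part of brain 1 was found in fat body 1 for 89.0%, and that of brain 2 in fat body 2 for 88.9%.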

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

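The direction comparison, the overlap divided by chance, the replicate block and the runs without sequence 1 were chosen after the result was seen. The odds ratio of tissue direction ran from 36.9 to 1064 and stayed above 1 with a p under 0.05 in every setting run, whereas the counts of tissue-only regions and the shares found again were not. Brain 2 with fat body 2 had the highest Jaccard index in every setting, but with an overlap of 50% the brain pair, at 0.0522, lay above brain 1 with fat body 1, at 0.0451. As the log2 of the index over chance, the difference of same-tissue and different-tissue pairs was -0.43, within the SD of 1.10 of the same-tissue pairs. With a −log10 q of at least 5 the share of fat body 2 found in fat body 1 was 36.4%, against 37.3%. With the same number of best peaks from each list there were 1676 brain-only and 743 fat-body-only regions, and the shares found again were 32.7% in brain and 15.9% in fat body, the lists being cut to the length of the shortest. With an overlap of 50% the counts were 1382 and 735 and the shares 20.6% and 13.5%. Summit windows gave shares of 32.0% and 28.7% and a same-tissue minus different-tissue Jaccard difference of -0.0387, against -0.0778. For the 50% overlap, the summit windows and the stricter q the cause was not tested. As a replicate block, only pairs with different numbers were compared, and the difference then turned to 0.0253; the cause was not tested. No model was fitted across libraries, so no other paired analysis was made. Leaving out 1 library moved the difference between -0.162 (without brain 1) and -0.00483 (without fat body 2). Calling a tissue from 1 library moved the brain-only count between 824 and 16887 and the fat-body-only count between 2744 and 83174: without brain 1 it was 1179 brain-only regions, without brain 2 it was 16887 and 3754 fat-body-only regions, without fat body 1 it was 3233 and 6175, and without fat body 2 it was 83174 fat-body-only regions. By construction, a tissue called from 1 library needs its regions in 1 list only, and an omitted library no longer excludes regions of the other tissue. No share within a tissue and no comparison of directions exists with a library left out. The promoter, gene list and motif alternatives were not run, for want of a genome and gene models of the build. A peak list gives no reads where no peak was called, so absence from the number 2 lists, with their lower background floor, may be lack of depth. The odds ratio of direction, 64.9 with a −log10 q of at least 5, compares tissues within a number, but this matches the floor only: per bp of the shortest peak the floor of fat body 1 was 2.17 times that of brain 1.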

Other observations

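The counts by sequence and position and the tests of a library swap, a batch, fewer open sites, lower depth and multi-copy sequence were chosen after the result was seen; those of list length and of the background in bins were not. Sequence 1, of 20.6 Mb, held fewer peaks per Mb than the average of sequences 2 to 28 in all 4 lists. The density was 65.2 against 82.4 peaks per Mb in brain 1 and 16.4 against 26.0 in brain 2, ratios of 0.791 (95% interval 0.749 to 0.836) and 0.629 (0.565 to 0.701). In fat body 1 it was 146 against 244 and in fat body 2 18.8 against 33.2, ratios of 0.598 (0.576 to 0.620) and 0.566 (0.512 to 0.626). No other long sequence had a lower density in any list. The lowest density of another long sequence was 68.0 in brain 1, close to sequence 1. It was 19.5 in brain 2, 230 in fat body 1 and 24.8 in fat body 2. Brain-only regions made up 38 of the 77 tissue-only regions of sequence 1, or 49.4% (37.8 to 61.0), and 23.7% (22.1 to 25.4) of those on sequences 2 to 28, an odds ratio of 3.13 (1.99 to 4.94). Of the 28 long sequences tested one by one with Fisher's exact test, sequence 1 alone passed Benjamini-Hochberg adjustment, at 6.47e-05, and the shares on the others ran from 14.3% to 36.6%. The 39 fat-body-only regions of sequence 1 were the fewest of any long sequence, the next being 54 on sequence 2. Its 38 brain-only regions were close to the 37 of sequence 4, so the raised share came mainly from few fat-body-only regions.

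The regions that brain 2 and fat body 2 shared and both number 1 lists lacked were placed differently along the sequences. Of the 4530 on long sequences, 30.1% (28.8 to 31.5) lay in the central 40% of the length, and their share was under 40% on 28 of 28 sequences. The share was 42.7% (41.9 to 43.5) for the regions of brain 1 and fat body 1 alone, 43.5% (40.5 to 46.5) for the regions in all 4 lists, 37.5% (33.7 to 41.3) for brain-only and 37.1% (35.0 to 39.2) for fat-body-only regions. The regions called in 1 number 2 list alone also had low central shares, 30.8% (26.2 to 35.7) in brain 2 and 32.4% (30.9 to 33.8) in fat body 2. The shares were 39.0% in brain 1 alone and 39.6% in fat body 1 alone. Among the classes counted, the low shares were thus those of number 2 regions that both number 1 lists lacked. The strongest of the regions of number 2 alone lay on BHWX01000023.1 from 11887596 to 11888839, with 37.2-fold enrichment in brain 2 and 44.5-fold in fat body 2.

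The libraries overlapped by number more than by tissue in the unscaled Jaccard index. A swap of brain 1 with fat body 2, which would exchange tissue and number, stays open. The direction odds ratio was above 1 both for tissue as labelled, at 49.7, and for number, at 2614. The labels rule out no shared factor behind either. Both odds ratios divide by the same regions and list lengths differed between numbers, so their sizes do not decide the question. Differing thresholds and list lengths also stay open: with the same number of best peaks from each list the same-tissue minus different-tissue difference was -0.0561. It met the limit set beforehand, below 0 by more than the SD of the same-tissue pairs, but by 4.33e-05 only, against an SD of 0.0561, so this is not taken to exclude them. Whether the number marks a batch was not decided, because the labels name none and the excess of 0.194 of the same-number over the different-number pairs restates the pattern.

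The low density on sequence 1 may reflect a sequence present in 1 copy in part of the nuclei. In silkworms females are ZW and chromosome 1 is the Z, but the sources used here say neither that sequence 1 is that chromosome nor which sex was dissected. The local background of its peaks was 0.857 and 0.832 of that elsewhere in brain 1 and brain 2, and 0.647 and 0.663 in fat body 1 and fat body 2; the lowest ratios of any other long sequence were 0.773 and 0.832 in brain, where sequence 1 did not stand apart, and 0.732 and 0.858 in fat body, where it lay below them. Fewer open sites at an unchanged read depth stay open in both tissues. The upper bounds of the background ratio were at most 0.913 in brain and 0.688 in fat body. The background at summits may, however, also hold reads of nearby open chromatin, which a peak list cannot separate. The median background was 8.36 and 4.14 in the fat body lists, against floors of 1.38 and 0.534, and the source of this gap was not tested. The background was below the rest in 21 of 21 bins of 1 Mb in both fat body lists, but in 20 and 17 of 21 in brain 1 and brain 2; the lowest share, 81.0%, was under the 90% and over the 70% set beforehand, so copy number and other sources of low background cannot be told apart, and a different sex mix of the tissues was not tested.

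The regions shared by brain 2 and fat body 2 and absent from number 1 cannot themselves test lower depth, since number 1 lacks them by definition. If the number 2 lists were shallower samples of the regions in the number 1 lists, their strongest peaks should lie in those lists. Of the strongest 10 percent, 29.7% in brain 2 and 39.5% in fat body 2 lay in the number 1 list of the same tissue. Of all peaks of brain 2 and fat body 2, 38.7% and 37.3% did. Neither list as a whole was thus a subset of the number 1 list of its tissue. The lists include the regions in question, so these shares partly restate the pattern. Reads from multi-copy sequence are a candidate explanation: 3.14% of the regions of brain 2 and fat body 2 alone lay on unplaced sequences. The odds ratio was 6.76 (5.63 to 8.12) against all other patterns. Unplaced position only stands in for multi-copy sequence here, and 4530 of these regions lay on long sequences. The peak names carry a mapping quality of 20, and whether a filter at that value removed reads of multi-copy sequence was not tested. Regions of fat body 2 alone had an odds ratio of 6.52 (5.28 to 8.06) against the patterns other than it and brain 2 with fat body 2 alone. The unplaced share was 2.59% for fat body 2 alone and 4.52% for brain 2 alone. It was at most 0.820% in any pattern that included a number 1 list. The excess was thus seen in number 2 regions that both number 1 lists lacked. Without the genome sequence no repeat was identified.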
